A study of Rattus norvegicus with 18 samples.

How the data were processed

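RNA from whole kidneys of rats was measured by RNA sequencing in 18 libraries, 6 per group. Per the labels, NC rats received no treatment, CKD rats received adenine at 100 mg per kg per day, and SZ rats received the same adenine dose with SZ-A at 300 mg per kg per day. The chemical nature of SZ-A is not given in the sources used here. Libraries were made with an Illumina TruSeq RNA kit from Trizol-extracted total RNA, per the labels' protocols. The labels name groups and replicate numbers but do not state that each library came from a separate animal, so p-values measure the spread between these libraries, which may be technical in part.

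The authors deposited 1 table of FPKM values (fragments per kilobase of gene and mapped fragments, scaled by depth) for 32116 genes. Reads were aligned with HISAT2 2.0.5 to the build mRatBN7.2, as far as the tools and build named in the submitters' processing notes tell. The counting program, its strand setting and the annotation release are not given in the sources used here. Because strand handling is not stated, antisense and overlapping genes cannot be told apart, and members of gene families with near-identical copies (such as the kallikreins and C4b) are uncertain. The table also holds 1556 unannotated loci, of which 546 passed the filter for testing.

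In every library each FPKM value multiplied by gene length was a whole multiple of 1 step, within a tolerance of 0.01, for 100% of values above 0. The step gives the number of reads per gene and the library size behind the deposited FPKM. Recovered totals ran from 15354358 to 18532375 reads per library. The sizes the authors divided by were not these totals: their ratio to the total averaged 0.896 in NC, 1.14 in CKD and 1.04 in SZ. Their largest difference from sizes by the median ratio to the geometric mean was 0%, and they differed by up to 4.94% from trimmed mean of M-values sizes computed here. The deposited scaling therefore centres most genes between groups, and a rescaling to plain totals moves the median gene.

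Genes were tested where FPKM was at least 1 in at least 6 of the 18 libraries, which left 13851 genes (12604 protein coding) and set aside 18265. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, in 1 fit of 3 group means over all 18 libraries with an intensity trend, 2-sided, with Benjamini-Hochberg adjustment within each comparison. A gene is called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale and understate the change of genes with low FPKM. Every adjusted p of a single gene comes from limma.

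A total of 35 gene lists for kidney cell types, injury, matrix, immune and metabolic genes held 612 symbols, of which 574 were found in the table and 507 were tested. Some genes stand in more than 1 list. The 29 lists with at least 5 tested members were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01 and again with the correlation estimated from the data. They were also tested with fry, which asks whether the members move, on balance, one way. The list score of a library is the mean log2(FPKM + 1) of the tested members, and its difference between groups was put to an exact 2-sided permutation test over 924 splits, for which 0.0022 is the smallest p possible. Adjusted p-values of lists are over the lists within a comparison.

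Named genes followed a rule. For CKD against NC and SZ against CKD it takes the 5 called genes with the largest and the 5 with the smallest log2 fold change among genes with a proper symbol, a mean FPKM of at least 1 and group ranges that do not overlap. It adds up to 2 called members of each of up to 8 lists with the smallest camera p, 13 genes named whatever their values, and the 5 genes per direction with the smallest adjusted p among those changed by adenine and moved back under SZ-A. The rule gave 60 genes, 31 for CKD against NC and 47 for SZ against CKD. Other members of a list are named where they moved against their list or where the list held no gene of the rule, and these were chosen after their values were seen.

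The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were another pseudocount (0.1), no low-value filter or a mean FPKM of at least 5, scaling to a fixed FPKM sum (TPM) or by median ratios or without the 20 most abundant genes, fitting only the groups compared, array weights, no intensity trend, robust variance, a fold limit of 2, an exact rank sum test, replicate number as a block, and leaving out each library in turn. Added after the data had been seen were limma's voom on the recovered reads, plain library totals, trimmed mean of M-values scaling, a lowess correction of each library for gene length with a span of 0.3, and leaving out CKD 2, CKD 5 and SZ 3.

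The limma and list steps were checked on simulated data for CKD against NC over 13851 genes. Of the genes changed by 1.5-fold, 23 of 50 were recovered. The recovery was 43 of 50 at 2-fold, 48 of 50 at 4-fold and 50 of 50 at 8-fold, and 11 of 13651 unchanged genes were called. Both shifted lists, proximal tubule transport and macrophages, were called, as were 2 of 27 other lists, and the shifted lists share members with others. Simulated genes varied independently of each other. The check therefore cannot judge camera at the preset correlation of 0.01, since estimated correlations in the data reached 0.71 (oxidative phosphorylation). No pair of libraries held identical values, and replicate pairs differed by a chi-square of 17.8 or more per gene, beyond counting noise. This does not tell separate animals from separate libraries of an animal, and each library was counted once without knowing which they are.

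Genes called in both CKD against NC and SZ against CKD share the CKD libraries, so opposite signs arise without any effect of SZ-A. The chance level came from 100 simulations. Before the data were examined the plan was to simulate unchanged SZ libraries against the CKD libraries as they are. Drawing SZ values around the observed CKD mean would have removed the chance part of that mean, so both groups were drawn around it from residuals of the fit. These residuals were pooled over all 18 libraries, NC included. A first version drew residuals without replacement. It was replaced by draws with replacement, which give higher chance counts, after its result had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.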

Results

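Kidney transcriptomes were compared between untreated rats (NC), rats given adenine at 100 mg per kg per day (CKD) and rats given the same adenine dose together with SZ-A at 300 mg per kg per day (SZ), with 6 libraries per group. Adenine overload is a standard way to produce tubular injury and chronic kidney disease in rodents. Depth was even, with recovered totals between 15354358 and 18532375 reads per library and no difference between groups (exact permutation p of 0.76 or more). On the first principal component the NC libraries lay apart, and CKD 1 lay at 8.94, within the range of the SZ libraries (-12.1 to 28.4).

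Transcripts of the mitochondrial chromosome took 19.4% of reads in NC (SD 3.28, n = 6), 10.3% in CKD (SD 3.61, n = 6) and 14.0% in SZ (SD 2.83, n = 6). The share differed between CKD and NC (exact permutation p = 0.0043, adjusted p = 0.023 over 21 comparisons of library measures) and between SZ and NC (exact p = 0.015, adjusted p = 0.045), while the difference between SZ and CKD did not pass (exact p = 0.087). The mean log2 value of the 13 mitochondrial mRNAs, a set formed after this was seen, was lower in CKD than in NC by a difference of -1.44 (exact p = 0.0022) and higher in SZ than in CKD by 0.80 (exact p = 0.022, unadjusted), with 12 of 13 above 0, a median of 0.66 and 1 called. Libraries also differed in how values followed gene length. The slope was that of each gene's deviation from its mean over the 18 libraries, so it is relative to the average library. It used protein-coding genes with a mean FPKM of at least 5. CKD 5, SZ 3 and CKD 2 had slopes of -0.31, -0.25 and -0.21 log2 units per doubling of gene length, CKD 1 had -0.10, and the others lay between 0.011 and 0.11. Annotated ribosomal RNA genes took 1741 ppm of reads in CKD 5 and 809 in CKD 6, against 248 or fewer in every other library. The group means were 548 ppm in CKD, 116 in NC and 138 in SZ (CKD against NC exact p = 0.022, adjusted p = 0.057; SZ against CKD exact p = 0.069, adjusted p = 0.14), so RNA quality that differs with the groups is not excluded.

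**Figure D1:**
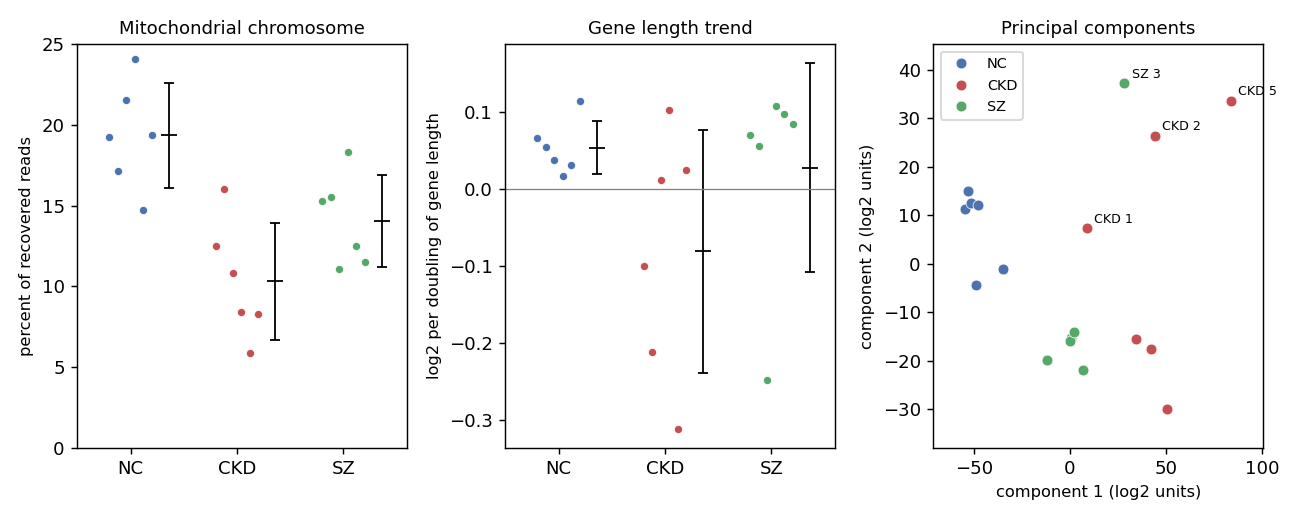
Each point is a library. The panels show the percent of recovered reads from the mitochondrial chromosome, the gene length slope, and the first and second principal components. The slope is that of each gene's deviation from its mean log2(FPKM + 1) over the 18 libraries, per doubling of gene length. Horizontal ticks with bars give the mean and SD of 6 libraries per group. CKD 5, SZ 3 and CKD 2 stand lowest in slope and highest on the second component.

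The comparison of CKD with NC asked what adenine changed. The kidney injury marker Havcr1 (KIM-1), which proximal tubule cells make after damage, rose from 0.680 FPKM (SD 0.434, n = 6) to 230 (SD 61.0, n = 6), a log2 fold change of 7.10 (SE 0.27, limma adjusted p = 5.7e-12). Osteopontin, encoded by Spp1, rose from 114 FPKM (SD 60.5) to 9344 (SD 1892), and Lcn2, the iron-carrier binding protein NGAL, from 2.14 (SD 1.17) to 146 (SD 101). Egf, a growth factor of the distal tubule, fell from 407 FPKM (SD 86.4) to 25.7 (SD 31.3), a log2 fold change of -4.53 (SE 0.45, adjusted p = 3.5e-07). Camera called 10 lists higher and 7 lower, but 0 with an estimated correlation (lowest adjusted p = 0.071), and the counts of genes in each list follow.

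In the tubular injury list 16 of 19 tested members rose and 0 fell, with the same counts when adjusted over the list alone, and the list median was 1.90 log2 units (camera adjusted p = 7.0e-10, and adjusted p = 0.071 with an estimated correlation). Of the extracellular matrix and fibrosis genes, 35 of 38 rose and 0 fell (35 and 0 adjusted over the list alone), with a median of 2.18 (camera adjusted p = 2.2e-16, and adjusted p = 0.15 with an estimated correlation). Among them Timp1, an inhibitor of matrix metalloproteinases, rose by 4.23 log2 units (SE 0.28), Col1a1 by 3.16 (SE 0.37) and Fn1 (fibronectin) by 2.77 (SE 0.24), and Postn (periostin) went from 0.0528 FPKM (SD 0.0405, n = 6) to 7.74 (SD 2.89, n = 6). In the fibroblast and mural cell list 7 of 12 rose and 1, Myh11, fell (7 and 1 adjusted over the list alone), and Acta2, the smooth muscle actin of myofibroblasts, rose by 0.73 (SE 0.24, adjusted p = 0.018). The camera adjusted p of that list was 0.0079, and adjusted p = 0.24 with an estimated correlation. In the TGF-beta signalling list 8 of 18 rose (9 adjusted over the list alone) and Bmp4, Bmp7 and Bambi fell. Its camera adjusted p was 0.077, with Tgfb1 up by 2.33 log2 units (SE 0.29, adjusted p = 3.2e-06).

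All 20 macrophage genes rose, also when adjusted over the list alone, with a median of 2.73 log2 units (camera adjusted p = 1.3e-15, and adjusted p = 0.11 with an estimated correlation). Gpnmb, a glycoprotein of activated macrophages, went from 0.641 FPKM (SD 0.298, n = 6) to 188 (SD 88.4, n = 6) and Lyz2 (lysozyme) from 128 (SD 28.8) to 1005 (SD 218). All 15 complement genes rose as well (15 adjusted over the list alone), with a median of 2.73, C4b by 4.54 log2 units (SE 0.21) and Cfi by 3.15 (SE 0.21). The complement list had a camera adjusted p of 1.2e-11, and adjusted p = 0.11 with an estimated correlation. Of the cytokine, chemokine and NF-kB genes 25 of 30 rose and 1, Ptgs2, fell (25 and 1 adjusted over the list alone). Their median was 1.26, with Il1rn, the interleukin 1 receptor antagonist, up by 4.17 (SE 0.30) and the monocyte chemokine Ccl2 by 3.26 (SE 0.26). The camera adjusted p was 1.6e-10, and adjusted p = 0.11 with an estimated correlation. Il19, a cytokine of the interleukin 10 family outside these lists, rose by 5.12 log2 units (SE 0.31) from 0.101 FPKM (SD 0.118).

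Among T and NK cell genes 10 of 15 rose and 1, the co-receptor gene Cd28, fell (11 and 1 adjusted over the list alone), with camera adjusted p = 5.3e-05 and adjusted p = 0.23 with an estimated correlation. In the interferon response list 14 of 19 rose and 0 fell (14 adjusted over the list alone), with camera adjusted p = 2.2e-05 and adjusted p = 0.24 with an estimated correlation. The B and plasma cell list (3 of 4 tested members up) and the neutrophil list (4 of 4 up) had too few tested members for a list test, and these counts were the same when adjusted over each list alone.

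In the cell cycle list 23 of 25 genes rose and 1, Tyms, fell (23 and 1 adjusted over the list alone). The replication helicase genes Mcm5 and Mcm3 rose by 1.85 (SE 0.15) and 1.95 (SE 0.17) log2 units. The list had a median of 1.02 and a camera adjusted p of 3.1e-11, with adjusted p = 0.11 under an estimated correlation. Of the apoptosis, necroptosis and senescence genes 13 of 21 rose and 1, Gsdme, fell (13 and 1 adjusted over the list alone), with a median of 0.66, camera adjusted p = 7.4e-05 and adjusted p = 0.11 with an estimated correlation.

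Of the proximal tubule transport genes 22 of 29 fell and 1, the glucose carrier gene Slc2a2, rose (22 and 1 adjusted over the list alone). Their median was -1.26 log2 units (camera adjusted p = 1.1e-05, and adjusted p = 0.24 with an estimated correlation). Slc34a1, the main phosphate carrier of this segment, went from 1674 FPKM (SD 226, n = 6) to 627 (SD 256, n = 6) and the organic anion carrier gene Slc22a6 from 549 (SD 58.8) to 154 (SD 84.7). In the loop of Henle and distal tubule list 15 of 20 fell and Trpv5, Cldn19 and Ptger3 rose (15 and 3 adjusted over the list alone), with camera adjusted p = 0.00025 and adjusted p = 0.18 with an estimated correlation. Umod (uromodulin) fell from 829 FPKM (SD 387) to 254 (SD 117). Of the collecting duct genes 15 of 17 fell and 0 rose (15 adjusted over the list alone), with camera adjusted p = 1.8e-06 and adjusted p = 0.23 with an estimated correlation. The anion exchanger gene Slc4a1 fell by 3.39 log2 units (SE 0.28) and the proton pump gene Atp6v1b1 went from 81.0 FPKM (SD 21.3) to 20.1 (SD 8.40). The tissue kallikrein genes Klk1, Klk1b3 and Klk1c4 fell by 3.55 (SE 0.44), 3.66 (SE 0.37) and 5.54 (SE 0.44), and reads may be split between these near-identical copies.

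Among fatty acid oxidation genes 26 of 30 fell and 0 rose (26 adjusted over the list alone), with a median of -0.98 log2 units (camera adjusted p = 5.0e-09, and adjusted p = 0.23 with an estimated correlation). Crat fell by 0.83 (SE 0.11) and Hadha, a subunit of the mitochondrial trifunctional protein, by 0.85 (SE 0.12). Of the gluconeogenesis and fructose genes 8 of 9 fell and 1, Pck2, rose (8 and 1 adjusted over the list alone), with camera adjusted p = 0.0014 and adjusted p = 0.23 with an estimated correlation. Oxidative phosphorylation genes of the nuclear genome had a median of -0.51 with 17 of 24 lower and 0 higher (17 adjusted over the list alone), camera adjusted p = 4.0e-05 and adjusted p = 0.39 with an estimated correlation. The share of mitochondrial reads was lower in the same libraries, as given above. Of the Klotho, vitamin D and mineral handling genes 7 of 13 fell and 1, Trpv5, rose (7 and 1 adjusted over the list alone), with camera adjusted p = 0.038 and adjusted p = 0.39 with an estimated correlation. The anti-ageing hormone gene Kl (Klotho) went from 84.3 FPKM (SD 14.4) to 33.9 (SD 15.2), a log2 fold change of -1.44 (SE 0.35, adjusted p = 0.0020).

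The other lists did not pass camera in this comparison. The exact score test and fry, which do not compare a list with other genes, passed for renin-angiotensin (score adjusted p = 0.0030, fry 4.7e-06), hypoxia and erythropoietin (0.0030, 0.0024), adipocytes (0.0030, 0.0023), TGF-beta signalling (0.0030, 0.00020), podocytes (0.014, 0.032), endothelium (0.019, 0.023) and the antioxidant response (0.024, 0.041), and the score test alone for glycolysis (0.035). Members went 2 up and 8 down of 12 for podocytes, 0 up and 4 down of 12 for endothelium, and 0 up and 5 down of 7 for renin-angiotensin genes. They went 2 up (Hmox1 and Gpx2) and 10 down of 21 for the antioxidant response, 0 up and 5 down of 11 for hypoxia and erythropoietin, and 4 up and 1 down of 12 for the unfolded protein response. They went 3 up and 1 down of 10 for immediate early and heat shock genes, 4 up and 2 down of 13 for glycolysis, and 2 up and 2 down of 14 for lipid and sterol synthesis. In the adipocyte list Fabp4 and Cfd rose and Adipoq (adiponectin) fell among 5 tested genes, and Fabp4 is also made by macrophages while Cfd encodes complement factor D. All counts in this paragraph were the same when adjusted over the list alone. The endothelium, antioxidant and hypoxia medians were -0.12, -0.28 and -0.18 as deposited and turned to 0.33, 0.18 and 0.22 under TPM scaling and to 0.22, 0.061 and 0.11 under plain totals. The endothelium median also turned, to 0.0058, without the 20 most abundant genes. In the purine metabolism list 4 rose and 5 fell of 14 (4 and 5 adjusted over the list alone). Aprt, which salvages adenine, rose by 0.66 log2 units (SE 0.19, adjusted p = 0.0080), and Xdh, which oxidises adenine to an insoluble product, had a log2 fold change of 0.21 (SE 0.14, adjusted p = 0.22). Erythrocyte (0 up and 2 down of 2 tested, Hba-a2 and Slc4a1) and aryl hydrocarbon receptor target lists (1 up, Cyp1b1, of 4) were too short to test, and 0 adrenal and 0 urothelium genes were tested.

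**Figure D2:**
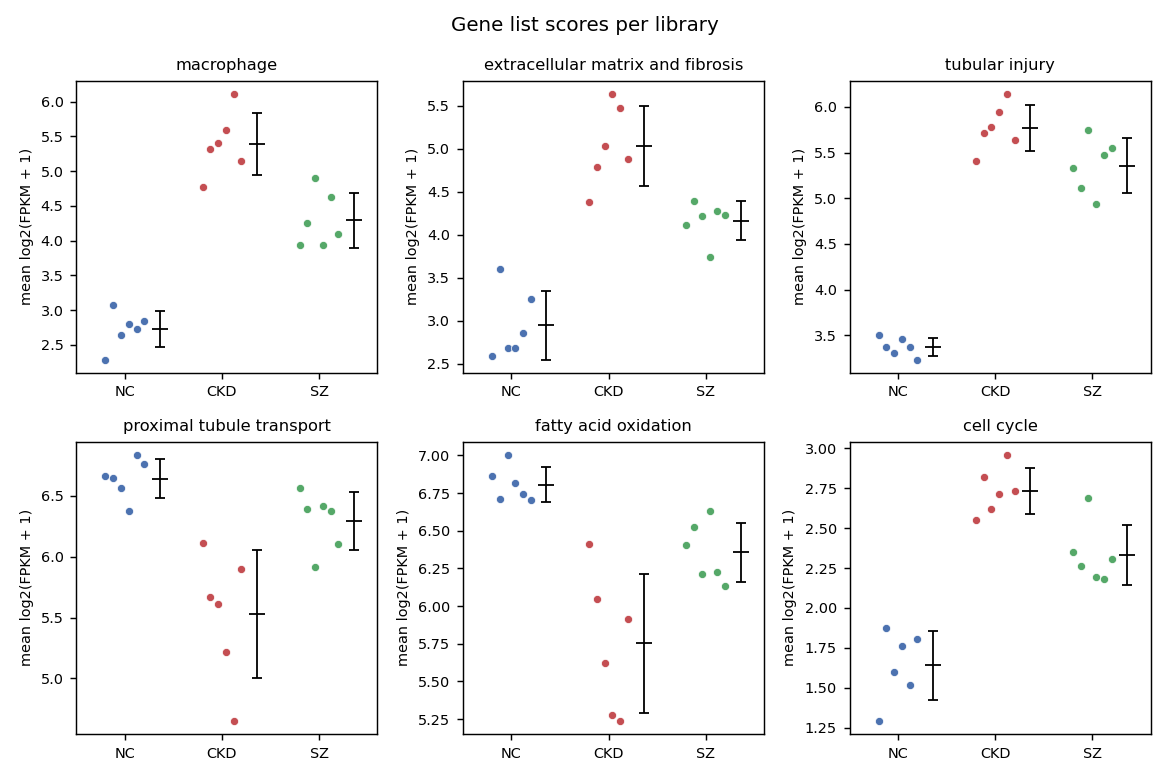
Each point is a library, at the mean log2(FPKM + 1) over the tested members of the list named above the panel, and horizontal ticks with bars give the mean and SD of 6 libraries per group. Macrophage scores were 2.73 (SD 0.262) in NC, 5.39 (SD 0.445) in CKD and 4.29 (SD 0.392) in SZ.

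By limma, 6973 of 13851 genes (50.3%) differed between CKD and NC, 3378 higher and 3595 lower, and 3664 genes (26.5%) had ranges that did not overlap, against 0.216% by chance. The balance of directions depends on scaling: 48.4% of called genes were higher as deposited, 83.6% under TPM scaling, 77.8% under plain totals and 62.4% without the 20 most abundant genes. The median of all genes was -0.040 as deposited, 0.37 under TPM scaling and 0.25 under plain totals. Camera called 17 of 29 lists, 10 up and 7 down, and 0 with an estimated correlation (8 lists at an unadjusted p under 0.05), while fry called 24 and the exact score test 25. All 17 lists called by camera had an exact score p of 0.0022, the smallest possible (adjusted p = 0.0030). At an unadjusted p under 0.05, 7866 genes passed. The median, mean and camera direction differed in sign for purine metabolism (0.044, 0.053 and down) and for lipid and sterol synthesis (0.0051, -0.036 and down).

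**Figure D3:**
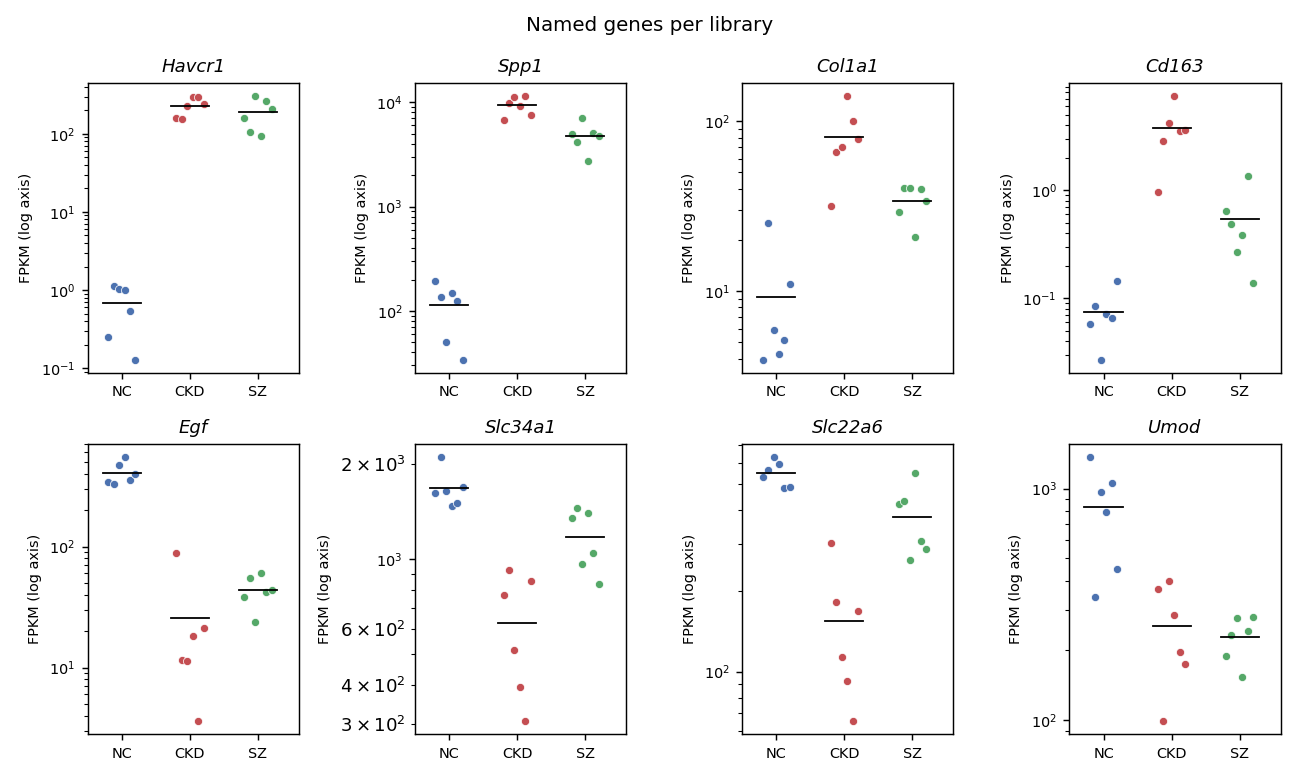
Each point is the FPKM of a library on a log axis and horizontal lines are the mean of 6 libraries per group. Havcr1 and Umod had similar means in CKD and SZ (230 and 189 FPKM, and 254 and 228 FPKM), whereas Slc22a6 and Cd163 moved back towards NC.

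The comparison of SZ with CKD asked what SZ-A changed in rats given adenine. Called lower in SZ were 17 of 20 macrophage and 20 of 38 matrix genes, and called higher were 12 of 29 genes of proximal tubule transport and 10 of 30 of fatty acid oxidation. Camera called these 4 lists, but none of them with an estimated correlation (adjusted p = 0.22 for each). Cd163, a scavenger receptor of macrophages, fell from 3.76 FPKM (SD 2.11, n = 6) to 0.547 (SD 0.431, n = 6), a log2 fold change of -1.54 (SE 0.24, limma adjusted p = 0.0027). Postn fell from 7.74 FPKM (SD 2.89) to 1.77 (SD 1.33), a log2 fold change of -1.72 (SE 0.24, adjusted p = 0.0021). Slc22a6 rose from 154 FPKM (SD 84.7) to 376 (SD 110), a log2 fold change of 1.41 (SE 0.28, adjusted p = 0.0070).

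Of the macrophage genes 17 of 20 fell and 0 rose (19 adjusted over the list alone). Their median was -1.20 log2 units, and the list score dropped by 1.10 (exact permutation p = 0.0043, adjusted p = 0.023; camera adjusted p = 1.7e-14, and adjusted p = 0.22 with an estimated correlation). Gpnmb fell by 1.84 (SE 0.34) and Lyz2 by 1.27 (SE 0.21). Ctsk, a collagen-degrading cathepsin, fell by 1.78 (SE 0.32). In the complement list 7 of 15 fell (10 adjusted over the list alone), with log2 fold changes of -1.40 (SE 0.29) for C1qa and -1.20 (SE 0.26) for C1qc, camera adjusted p = 1.1e-06 and adjusted p = 0.22 with an estimated correlation. Of the cytokine, chemokine and NF-kB genes 10 of 30 fell and 1, Cx3cl1, rose (19 and 1 adjusted over the list alone), with camera adjusted p = 2.4e-06 and adjusted p = 0.22 with an estimated correlation. Cxcl2, a neutrophil chemokine, fell by 1.27 log2 units (SE 0.25), Il1rn by 1.39 (SE 0.30) and Ccl2 by 1.01 (SE 0.26). Among T and NK cell genes 4 of 15 fell (5 down and 1 up adjusted over the list alone), with camera adjusted p = 0.015 and adjusted p = 0.43 with an estimated correlation. Il19 fell by 1.84 (SE 0.31) and its family member Il24 by 1.60 (SE 0.22).

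Of the matrix genes 20 of 38 fell and 0 rose (26 adjusted over the list alone), with a median of -0.94 log2 units, a score that dropped by 0.87 (exact permutation p = 0.0043, adjusted p = 0.023), camera adjusted p = 2.4e-14 and adjusted p = 0.22 with an estimated correlation. Ccn2 (connective tissue growth factor) stood at 53.5 FPKM (SD 13.9) in NC and 48.1 (SD 11.6) in CKD, not past the test, and fell to 22.3 (SD 3.34) in SZ, a log2 fold change of -1.06 against CKD (SE 0.17, adjusted p = 0.0024). Col1a1 had a log2 fold change of -1.13 (SE 0.37, adjusted p = 0.054) and did not pass, and Fn1 (-0.77, SE 0.24, adjusted p = 0.048) and Tgfb1 (-0.94, SE 0.29, adjusted p = 0.041) passed narrowly. Over the alternatives other than the rank sum test and the fold limit, the adjusted p ran from 0.016 to 0.11 for Fn1 and from 0.0030 to 0.11 for Tgfb1. Fn1 passed in 11 of these 34 settings, single left-out libraries included. In the TGF-beta signalling list 5 of 18 fell and 1, Bmp4, rose (9 and 2 adjusted over the list alone), and in the fibroblast and mural cell list 2 of 12 fell (4 adjusted over the list alone). Their camera adjusted p-values were 0.038 and 0.016, each with adjusted p = 0.29 under an estimated correlation. Twist2, a transcription factor of mesenchymal cells, fell by 1.74 (SE 0.28) and Ca3 (carbonic anhydrase 3) by 2.18 (SE 0.35).

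In the cell cycle list 6 of 25 fell (15 adjusted over the list alone), Plk1 by 0.67 log2 units (SE 0.16) and Bub1 by 0.45 (SE 0.11), with camera adjusted p = 3.6e-07 and adjusted p = 0.22 with an estimated correlation. Among apoptosis, necroptosis and senescence genes 5 of 21 fell and 1, Gsdme, rose (7 and 1 adjusted over the list alone), with camera adjusted p = 0.0071 and adjusted p = 0.22 with an estimated correlation. Immediate early and heat shock genes had a median of -1.14, with 2 of 10, Fos and Dnajb1, past the test (6 adjusted over the list alone), camera adjusted p = 0.0020 and adjusted p = 0.29 with an estimated correlation.

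Of the proximal tubule transport genes 12 of 29 rose and 0 fell (17 adjusted over the list alone), with a median of 0.85 log2 units and a score higher by 0.77 (exact permutation p = 0.0065, adjusted p = 0.023, camera adjusted p = 9.9e-10, and adjusted p = 0.22 with an estimated correlation). Slc34a1 rose by 0.99 (SE 0.25, adjusted p = 0.018) and the sulfate carrier gene Slc26a1 by 1.05 (SE 0.20). Among fatty acid oxidation genes 10 of 30 rose and 0 fell (19 adjusted over the list alone), with a median of 0.54, camera adjusted p = 8.1e-10 and adjusted p = 0.22 with an estimated correlation. Cyp4a2, a fatty acid hydroxylase, rose by 1.06 log2 units (SE 0.26) and Crat by 0.44 (SE 0.11). Of the collecting duct genes 5 of 17 rose (10 adjusted over the list alone), among them Slc4a9 by 1.11 (SE 0.24) and Insrr by 1.02 (SE 0.25), with camera adjusted p = 0.00026 and adjusted p = 0.29 with an estimated correlation. Gluconeogenesis and fructose genes (3 of 9 up, 7 adjusted over the list alone) and Klotho, vitamin D and mineral handling genes (1 of 13 up, 6 adjusted over the list alone) had camera adjusted p-values of 0.00035 and 0.00029, each with adjusted p = 0.22 under an estimated correlation.

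The loop of Henle and distal tubule list (2 of 20 up, 5 adjusted over the list alone), the antioxidant response (5 of 21 up, 6 adjusted over the list alone) and oxidative phosphorylation (1 of 24 up, 0 adjusted over the list alone) had camera adjusted p-values of 0.013, 0.019 and 0.015. With an estimated correlation their adjusted p-values were 0.29, 0.37 and 0.60, by the exact score test 0.089, 0.094 and 0.41, and by fry 0.052, 0.085 and 0.31. The exact score test also did not pass for T and NK cells (adjusted p = 0.13) and for the Klotho, vitamin D and mineral handling list (adjusted p = 0.071). The oxidative phosphorylation median of 0.13 turned to -0.041 under TPM scaling and to -0.00093 under plain totals. The 5 largest rises by the naming rule were those of Pzp, Dusp15, Prima1, Abcb1b and Paqr7, between 1.15 (SE 0.21) and 1.46 (SE 0.27) log2 units.

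Several injury genes did not pass between SZ and CKD. Havcr1 was 189 FPKM in SZ (SD 85.0, n = 6) against 230 in CKD (SD 61.0, n = 6), a log2 fold change of -0.37 (SE 0.27, limma adjusted p = 0.38), and Umod was 228 (SD 49.2) against 254 (SD 117). Spp1 (-0.99, SE 0.35, adjusted p = 0.072), Lcn2 (-1.27, SE 0.45, adjusted p = 0.072), Kl (0.88, SE 0.35, adjusted p = 0.10), Acta2 (-0.58, SE 0.24, adjusted p = 0.12), Aprt (-0.48, SE 0.19, adjusted p = 0.11) and Xdh (0.091, SE 0.14, adjusted p = 0.69) did not pass either. In the tubular injury list as a whole 5 of 19 fell, Krt8, Cd44, Vim, Cdkn1a and Anxa2 (9 down and 2 up adjusted over the list alone). The list had a median of -0.37, camera adjusted p = 0.0040 and adjusted p = 0.23 with an estimated correlation, and its exact score test gave p = 0.030 (adjusted p = 0.063).

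By limma, 1521 of 13851 genes differed between SZ and CKD, 576 higher and 945 lower, and 313 (2.26%) had ranges that did not overlap, against 0.216% by chance. Of the calls 37.9% were higher as deposited, 14.5% under TPM scaling, 17.7% under plain totals and 51.0% under trimmed mean of M-values scaling. The median of all genes was 0.0055 as deposited, -0.13 under TPM scaling and -0.10 under plain totals. Camera called 19 of 29 lists, 8 up and 11 down, and 0 with an estimated correlation (lowest adjusted p = 0.22, 2 lists at an unadjusted p under 0.05), while fry called 16 and the exact score test 13.

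The size of the SZ against CKD count depends on which single library is left out: it was 533 without SZ 4, 669 without CKD 5, 831 without SZ 1, 850 without SZ 2, 1010 without CKD 3, 2798 without CKD 1 and 3058 without SZ 3. It was 554 when limma was fitted to the SZ and CKD libraries alone and 2830 with array weights. The main fit shares 1 estimate of spread per gene with the NC libraries, so its p-values rest in part on the spread in NC. For proximal tubule transport the list score had an SD of 0.16 in NC against 0.52 in CKD. CKD had the larger SD in most other lists too, such as fatty acid oxidation (0.11 in NC against 0.46) and oxidative phosphorylation (0.038 against 0.39). In a minority of lists the order was reversed, as for the collecting duct (0.38 against 0.31) and the cell cycle (0.22 against 0.14). Whether this accounts for the 554 was not tested. The exact rank sum test called 0 genes (lowest adjusted p = 0.096), with 3052 genes at an unadjusted p under 0.05 against 4014 by limma. Its p cannot go below 0.0022 here, a value reached by the 313 genes whose ranges did not overlap. The exact score test called 0 lists without SZ 1, without SZ 2, without SZ 4, or without CKD 2, CKD 5 and SZ 3 together, where 14, 13, 14 and 14 lists had an unadjusted p under 0.05 and camera called 16 or more lists. Log2 fold changes of SZ against CKD rose with gene length across genes (Spearman's rho 0.20, genes not being independent replicates). Of the 47 named genes called here, 31 were called in every other setting that tested them apart from the rank sum test and the fold limit, Cd163, Postn, Ccn2, Slc22a6, Slc26a1 and Plk1 among them. Most named genes were picked by their values in these same data, so this share does not speak for the other calls.

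The comparison of SZ with NC gave what remained different from untreated kidneys. Havcr1 stayed higher in SZ by 6.73 log2 units (SE 0.27, limma adjusted p = 1.5e-11), Spp1 by 5.55 (SE 0.35) and Lcn2 by 4.05 (SE 0.45). Egf was lower by a log2 fold change of -3.22 (SE 0.45, adjusted p = 7.9e-05) and Umod by -1.73 (SE 0.35, adjusted p = 0.0016). Slc34a1 (-0.53, SE 0.25, adjusted p = 0.13), Slc22a6 (-0.59, SE 0.28, adjusted p = 0.14), Kl (-0.56, SE 0.35, adjusted p = 0.26) and Cd163 (0.48, SE 0.24, adjusted p = 0.17) did not pass. Not passing does not show a return to NC levels.

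The tubular injury list was higher in 14 of 19 genes and lower in 0 (15 adjusted over the list alone), with a median of 1.60 log2 units and a camera adjusted p of 5.7e-16. It was the only list of the 3 comparisons that camera still called with an estimated correlation (adjusted p = 0.0071). Higher genes made up 31 of 38 in the matrix list (33 adjusted over the list alone, estimated-correlation adjusted p = 0.16) and 19 of 20 in the macrophage list (19, adjusted p = 0.086). They made up 15 of 15 in the complement list (15), 19 of 30 in the cytokine list (22) and 19 of 25 in the cell cycle list (20), each with an estimated-correlation adjusted p = 0.083. Lower in SZ than in NC were Mmp9 and Ccn2 of the matrix list, Ptgs2 of the cytokine list and Tyms of the cell cycle list. In the collecting duct list 11 of 17 were lower (12 adjusted over the list alone, p = 0.18 with an estimated correlation), and in the loop of Henle and distal tubule list 12 of 20 were lower and Trpv5 and Ptger3 higher (15 and 3 adjusted over the list alone, p = 0.14 with an estimated correlation). Of the proximal tubule transport genes 2 were higher and 2 lower of 29 (1 and 2 adjusted over the list alone, camera adjusted p = 0.064), while the list median was -0.45 and the score difference of -0.35 passed the exact permutation test (p = 0.013, adjusted p = 0.020) but not fry (adjusted p = 0.26). Of the fatty acid oxidation genes 5 of 30 were lower (4 adjusted over the list alone, camera adjusted p = 2.4e-05, and adjusted p = 0.43 with an estimated correlation).

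By limma 2919 genes (21.1%) differed between SZ and NC, 1726 higher and 1193 lower, and 2016 (14.6%) had ranges that did not overlap, against 0.216% by chance. Of the calls 59.1% were higher as deposited, 92.6% under TPM scaling, 88.4% under plain totals and 80.9% without the 20 most abundant genes. With array weights 5492 genes were called, 2716 higher and 2776 lower. Fitted to the SZ and NC libraries alone, limma called 4040, 2123 higher and 1917 lower. The p-values of the main fit rest in part on the spread in CKD, so 2919 may understate what remained different. The median of all genes was -0.035 as deposited, 0.24 under TPM scaling and 0.15 under plain totals. Camera called 16 lists, 11 up and 5 down, and 1, tubular injury, with an estimated correlation (9 lists at an unadjusted p under 0.05), while fry called 17 and the exact score test 20.

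Most genes that differed between SZ and CKD had been changed by adenine in the other direction. Of the 1521 genes, 1453 (95.5%) moved back, 66 were not called in CKD against NC, and 2 moved further the same way: Sgk1 was lower and Mybpc2 higher in both comparisons. Among genes raised by adenine and lower in SZ, those with the smallest adjusted p were Postn, Tifa, Il24, Samsn1 and Fibin. Fibin went from 0.646 FPKM (SD 0.311, n = 6) in NC to 3.80 (SD 1.46) in CKD and 0.835 (SD 0.411) in SZ. Among those lowered by adenine and higher in SZ they included Gosr2, Xylb, Glyctk and Slc25a42, and Gosr2 stood at 87.8 FPKM (SD 9.10) in NC, 48.0 (SD 11.4) in CKD and 89.4 (SD 11.5) in SZ. Of the 3378 genes raised by adenine 26.8% moved back and 1662 (49.2%) were still higher in SZ than in NC. Of the 3595 lowered genes 15.2% moved back and 1086 (30.2%) were still lower. The 2 classes overlap, and moving back is not full return: 561 of the 906 raised genes that moved back were still called higher in SZ than in NC. Of the 547 lowered genes that moved back, 155 were still called lower. The split by direction depends on scaling: 906 raised and 547 lowered genes moved back as deposited, 763 and 763 under trimmed mean of M-values scaling, and 1643 and 254 under TPM scaling.

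Both comparisons use the CKD libraries, which alone makes opposite signs. With unchanged SZ groups the simulated number of genes moved back averaged 12.8 and reached 838 at most, and independent lists would give 380 opposite and 386 same-direction genes. The simulated groups drew on residuals of all 18 libraries, so their spread need not be that of the CKD libraries. Where NC libraries vary less than CKD libraries, the simulated counts are too low as a chance level. Same-direction genes averaged 0.14 in these simulations and reached 8 at most. A near absence of same-direction genes therefore arises without any effect of SZ-A, and the share of 95.5% is by itself no sign of reversal. The correlation of the fold changes across genes was -0.85 (simulated mean -0.15, lowest -0.83) and their covariance -0.27 (simulated mean -0.030, lowest -0.29). With 3 separate CKD libraries for each comparison the median number moved back was 482 (0 to 2172 over 20 splits) and the correlation -0.72. The count was 512 without SZ 4, 641 without CKD 5, 798 without SZ 1, 812 without SZ 2, 962 without CKD 3, 2678 without CKD 1 and 2780 without SZ 3.

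Positions are those of the deposited table on mRatBN7.2, each covering a protein-coding gene. Havcr1 (ENSRNOG00000007243) lies on chromosome 10 from 31119088 to 31151698, Spp1 (ENSRNOG00000043451) on chromosome 14 from 5308885 to 5315162, and Egf (ENSRNOG00000053979) on chromosome 2 from 218219415 to 218302064. Postn (ENSRNOG00000012660) lies on chromosome 2 from 138527696 to 138559099, Cd163 (ENSRNOG00000010253) on chromosome 4 from 157085093 to 157117878, and Ccn2 (ENSRNOG00000015036) on chromosome 1 from 20802199 to 20805734. Slc34a1 (ENSRNOG00000015262) lies on chromosome 17 from 9218876 to 9233852, Slc22a6 (ENSRNOG00000018215) on chromosome 1 from 205522729 to 205531173, Umod (ENSRNOG00000015557) on chromosome 1 from 173816339 to 173830302, and Kl (ENSRNOG00000001092) on chromosome 12 from 490399 to 530080.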

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

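Of the tests in this part, those of the gene length trend and of the 3 libraries with the steepest trend on the SZ against CKD calls, of scaling, gene length and tubule cell share on the mitochondrial mRNAs, and of dilution and scaling on the tubule and immune lists were chosen after the results were seen. The counts of other splits were set before.

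Among 100 splits of the NC and CKD libraries, the real split included, 1 gave as many called genes as the real 6973 (highest other 4473). For SZ against NC it was 1 of 100 (2919, highest other 207), and for SZ against CKD 2 of 100 (1521, highest other 3102). A result of 1 in 100 is the lowest these splits can give, and the libraries exchanged may not be separate animals. Counts as large as 6973 and 2919 were therefore rare among the splits, but chance is not excluded. The split with 3102 genes exchanges CKD 4 and SZ 3 and sorts the libraries by their gene length slope, which is 0.024 or lower in all of one side and 0.056 or higher in all of the other. A structure that goes with this slope therefore separates these libraries by more genes than the labels do. For genes moved back under SZ-A it was 2 of 100 (1453, highest other 2421). For the number of lists called by camera such counts were not rare: 18 of 100 splits gave as many as the real 17 in CKD against NC (highest other 21), 5 of 100 as many as 19 in SZ against CKD (highest other 21), and 19 of 100 as many as 16 in SZ against NC (highest other 19). Chance is not excluded there either.

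A library stood far from the other 5 of its group in 12 of 288 sets of values, and chance gives about 1 in 20, or 14.4 here. SZ 3 was concerned in 5 of them. Its gene length slope was -0.25 (others 0.056 to 0.11), its podocyte score 2.81 (others 3.69 to 3.86), its antioxidant response score 7.26 (others 6.79 to 6.96), its cell cycle score 2.69 (others 2.18 to 2.35) and its Kl level 21.4 FPKM (others 52.4 to 74.4). Kl was also low in CKD 5, at 8.85 FPKM (others 27.8 to 53.0). Ribosomal RNA genes took 248 ppm of reads in SZ 6 (others 93.8 to 140). The gluconeogenesis and fructose score was 7.35 in NC 5 (others 7.03 to 7.11). Samsn1 was 8.08 FPKM in CKD 2 (others 4.66 to 5.59), Cxcl2 was 1.11 in NC 6 (others 0 to 0.195), Fibin was 1.64 in SZ 2 (others 0.541 to 0.870) and Il19 was 2.41 in SZ 4 (others 8.39 to 15.3).

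Genes called between SZ and CKD were weighed against the trend with gene length, since short genes stood higher in CKD 2, CKD 5 and SZ 3. After each library was corrected for the trend, 94.3% of the called genes were still called in the same direction, with a median absolute log2 fold change of 0.67 against 0.69. Without the 3 libraries 67.5% were still called, with a median of 0.62, but of the 1521 genes 661 were without CKD 5 alone, 1493 without SZ 3 alone, and 531 without SZ 4, whose slope of 0.11 is not among the steep ones. Most calls therefore did not rest on the mean trend with length, but the correction cannot exclude other effects of whatever made these libraries differ. Leaving out the 3 libraries cannot decide it, since fold changes still rose with gene length without them (Spearman's rho 0.14, against 0.20 with all libraries). How many calls rest on single libraries, with or without the trend, stays open. What made these libraries differ, and whether it came with the treatment, stays open.

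Lower mRNAs of the mitochondrial genome in CKD were weighed as well, with 12 of the 13 called lower than in NC (Mt-nd3 being the exception) and a median log2 fold change of -1.38. Under plain library totals the median was -1.03 (SD 0.45 over the 13) and after the gene length correction -1.47 (SD 0.43). The SD over the 13 is not the spread between libraries. The share of reads from the mitochondrial chromosome, which rests on plain totals, was also lower in CKD (exact permutation p = 0.0043), so the deposited scaling does not account for it. After the gene length correction the median stayed below 0, but no test between libraries was run. The mean of the 13 fell by 0.33 more than the proximal tubule transport score, a difference of -0.33 with an exact permutation p of 0.20. A lower share of proximal tubule cells and lower levels within cells therefore cannot be told apart, because whole kidneys mix these cell types and the difference lies within the spread. The effect of adenine itself stays among the open explanations.

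Lower tubule lists with higher immune and matrix lists in CKD could come from dilution, since a smaller share of tubule cells raises the markers of every other cell type alike. The macrophage score rose by 2.90 log2 units more than the endothelium score (exact permutation p = 0.0022, the smallest possible), which dilution alone forbids. Under plain library totals the proximal tubule transport median was -0.92 (exact p of its score 0.0043) and the macrophage median 3.02 (exact p 0.0022), so the deposited scaling is not the cause either. A change that came with adenine, in the number of macrophages, in the genes cells express, or in both, remains a hypothesis, and these were not separated here. RNA quality that differs with the groups was not tested against these lists and stays open too.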

How the results depend on the processing

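Voom on recovered reads, plain totals, trimmed mean of M-values, the gene length correction and leaving out CKD 2, CKD 5 and SZ 3 were chosen after the data had been seen. In all 21 settings were tried besides leaving out each of 18 libraries, not every setting on every result, and lists were run under fewer settings than genes. Under those run on it no called named gene or list turned its direction in the test, though the median of the oxidative phosphorylation list in SZ against CKD fell below 0 under TPM scaling and plain totals. In CKD against NC all 58 called named genes stayed called in every setting that tested them other than the rank sum test and the fold limit, in SZ against CKD 31 of 47 and in SZ against NC 34 of 39. Apart from the 13 genes named whatever their values, these were picked by their values in CKD against NC or SZ against CKD. Their staying called therefore says little about the stability of other calls. Of the lists, 16 of 17, 13 of 19 and 13 of 16 were lost only with an estimated correlation. Limma voom on the recovered reads, which were whole for 100% of values, called 6842, 1517 and 2719 genes in the 3 comparisons. Median ratio scaling moved almost nothing, since the deposited sizes are already of that kind, and says nothing on stability.

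With a mean FPKM of at least 5, 4447 genes were called in CKD against NC and 1627 in SZ against NC, as fewer genes were tested. A fold limit of 2 left 2199, 297 and 682 genes in CKD against NC, SZ against CKD and SZ against NC, by its construction. With the limit set on CKD against NC alone and none on SZ against CKD, 935 genes moved back. Fitted to the 2 groups compared alone, limma called 554 genes in SZ against CKD and 4040 in SZ against NC. With array weights the counts were 2830 and 5492. The exact rank sum test called 0 genes in SZ against CKD (3052 at an unadjusted p under 0.05). With an estimated correlation camera called 0, 0 and 1 lists. Leaving out CKD 2, CKD 5 and SZ 3 left 0 list score differences in SZ against CKD (14 at an unadjusted p under 0.05), and with 3 separate CKD libraries for each comparison 482 genes moved back, with fewer samples. With 6 libraries per group the rank sum test cannot give a p below 0.0022. The 313 genes that reached it in SZ against CKD were too few to pass the adjustment over 13851 genes. The cause was not tested for the array weights, estimated correlation and 2-group values.

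With 1 library left out, genes called ran from 6372 to 7387 in CKD against NC, 533 to 3058 in SZ against CKD and 2186 to 3365 in SZ against NC. Lists called ran from 17 to 18, 16 to 20 and 14 to 18, list score differences from 24 to 26, 0 to 19 and 19 to 21, and genes moved back from 512 (without SZ 4) to 2780 (without SZ 3). The 533 genes were without SZ 4 and the 3058 without SZ 3, and the 0 list score differences without SZ 1, SZ 2 or SZ 4.

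Same-numbered libraries of different groups correlated between -0.36 and 0.23 in their deviations, 4 of 18 pairs over 0.1, and 1 of 18 libraries matched best with its own number, so the numbers do not pair the libraries. With replicate number as a block 6636, 1195 and 2584 genes, 18, 18 and 17 lists and 1148 genes moved back were counted. At 15354358 to 18532375 reads per library, the simulation recovered 23 of 50 genes changed by 1.5-fold in CKD against NC, so smaller changes could be missed at this depth and spread.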

Other observations

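The genes and groups in this part were chosen after their values were seen, and no test of an explanation was run on them. Not every change of the adenine-treated kidney was smaller with SZ-A. The fibrinogen genes rose with adenine and were no lower in SZ: Fga stood at 6.96 FPKM in NC (SD 2.11, n = 6), 43.6 in CKD (SD 20.8) and 84.5 in SZ (SD 41.5), Fgb at 0.698, 24.2 and 33.6, and Fgg at 0.149, 5.33 and 6.80, and all 3 were called in SZ against NC but not in SZ against CKD (limma adjusted p = 0.13, 0.63 and 0.61). Trpv6, an epithelial calcium channel, rose from 0.294 FPKM (SD 0.204) to 6.73 (SD 1.82) and stood at 6.93 (SD 1.26) in SZ. Ptgs2 (cyclooxygenase 2) fell from 6.82 FPKM (SD 5.35) to 0.622 (SD 0.537) and stood at 0.653 (SD 0.344) in SZ.

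Some genes of the circadian clock, picked by their values and not tested as a list, were called in SZ against CKD and others were not. Nr1d1 stood at 17.2 FPKM in NC (SD 5.53, n = 6), 8.56 in CKD (SD 3.96) and 17.0 in SZ (SD 1.93), a log2 fold change of 1.01 for SZ against CKD (SE 0.24, limma adjusted p = 0.015). Hlf (1.14, adjusted p = 0.021), Tef (0.82, adjusted p = 0.035), Dbp (1.24, adjusted p = 0.030), Per3 (0.85, adjusted p = 0.0078), Per2 (0.57, adjusted p = 0.040) and Nr1d2 (0.53, adjusted p = 0.040) were also higher in SZ, and Bhlhe41 was lower (-1.15, adjusted p = 0.0074). Per1 (-0.53, adjusted p = 0.20), Arntl (-0.41, adjusted p = 0.24) and Clock (0.44, adjusted p = 0.23) did not pass. The hour at which kidneys were taken is not given in the sources used here. Among glucocorticoid-induced genes, Fkbp5 was higher in CKD than in NC (log2 fold change 0.77, SE 0.18) and lower in SZ than in CKD (-0.89, SE 0.18), Zbtb16 went from 1.01 FPKM (SD 0.317) in NC to 3.58 (SD 2.04) in CKD and 0.451 (SD 0.309) in SZ, whereas Sgk1, induced by the same hormones, went from 79.6 (SD 20.4) to 43.6 (SD 12.5) and 24.8 (SD 6.26).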
